A study of Mus musculus with 6 samples.

How the data were processed

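The 6 libraries are 3' single-cell libraries (10x version 3) of cells sorted for tdTomato from heart and brain of Tbx18CreER;Rosa26tdTomato mice, 1 library for each of heart sham, heart infarct, heart peri-infarct, brain sham, brain infarct and brain peri-infarct. The deposited files hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 3.0.2 on the mm10 genome, per the file headers and the submitters' processing notes, which also name Seurat 3 for their later steps. Each file lists 31053 genes and only barcodes called as cells, with a lowest total of 500 UMIs or slightly more (751 in heart sham). Empty droplets and the tdTomato transcript itself were not used here. Gene positions come from the GENCODE vM21 annotation of mm10.

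Cells were kept with at least 500 genes detected and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0 cells in heart sham and in heart infarct, so the highest scores were marked instead, in the share expected from the number of barcodes (0.8% per 1000 barcodes). That left 11575, 8000 and 7293 heart cells and 2586, 2032 and 2290 brain cells, in the order sham, infarct and peri-infarct. The 3 libraries of an organ were clustered together without batch integration, on 2000 highly variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1.0 and seed 1 (scanpy with igraph 0.11.9, numpy 2.4.6, Python 3.11.15). Cells were linked by the neighbours they share, and principal components came from the eigenvectors of the covariance of scaled genes. A cluster took the name of the marker list with the highest mean log2 ratio over the lower quartile of clusters, with a pseudocount of 10 CPM. The name required a mean of at least 1, at least 3 markers 2-fold above that base at 20 CPM or more, at least 1 marker among the 10 leading genes of the cluster, and no other list with more markers among them. The rule on leading genes was changed after a first version misnamed clusters. Clusters that did not meet all of these stayed unnamed. Numerical settings of the linear algebra library were fixed, because doublet scores and the heart clusters moved slightly with them. Pericyte-like and other names describe transcripts, not lineage.

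Counts were summed over the cells of a class in each library and scaled to a total of 1000000 (CPM). A gene was tested when its mean CPM over both libraries was at least 50, and counted as higher or lower when the ratio of (CPM + 1) was at least 2-fold. Sums carry exact Poisson and shares exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only. With 1 library per group there is no test across samples, and cells were not used as replicates. Classes with fewer than 50 cells in a library were replaced by pericyte-like and smooth-muscle-like cells together, a rule set before the data were examined. For shares of cells with a UMI each cell was thinned to 1000 UMIs, shallower cells were left out, and the same share in endothelial-like cells is given as background. A fold against 0 counts uses a floor of 3 counts.

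The 21 response lists, fixed before the data were examined, cover fibrillar collagens, matrix glycoproteins, collagen processing, matrix proteases and inhibitors, basement membrane, contractile, TGF-beta signalling, angiogenic and pericyte-endothelial signalling, vasoactive receptors and channels, integrins and adhesion, interferon response, cytokines and inflammation, complement, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, dissociation stress, endoplasmic reticulum stress and secretion, osteochondral, adipogenic and neural progenitor genes. A list's median log2 ratio is set against 10000 random lists, each member replaced by 1 of the 100 genes nearest in mean expression. Lists with fewer than 3 tested members have no median. Genes named in the text follow a rule set before the data were examined: the 10 highest and 10 lowest ratios of each comparison with sham, leaving out ribosomal, mitochondrial, predicted and haemoglobin genes; 8 genes always named (Tbx18, Pdgfrb, Col1a1, Col3a1, Postn, Fn1, Acta2 and Mki67); up to 4 members per list; and the 10 genes shared by heart and brain with the largest smaller ratio. Genes outside the rule, such as those of the fibroblast-like cells, were chosen after their values were seen. Results for some genes that the rule selects are not reported here.

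The 15 alternatives chosen before the data were examined cover the filters on genes and mitochondrial UMIs per cell, doublets, edgeR TMM factors (edgeR 4.0.16, R 4.3.3), cell-wise means, thinning, the clustering, the class of cells, the CPM filter and the pseudocount. Another 5 were added after the data were seen. A list median within 0.5 log2 units of the reported one counts as unchanged. For the subtraction of free RNA, the free share of a library is the CPM of fibroblast markers in endothelial-like cells divided by their CPM over all cells of the library. It came to 43.8% in heart sham and between 1.70% and 3.49% in the other 5 libraries, and the library's profile was taken off each class in that share. This treats all fibroblast markers in endothelial-like cells as free RNA. All tests of explanations were chosen after the results were seen. The test of free RNA in brain infarct was first a bound from the whole library profile (lowest ratio 12.99), and was replaced by the ratio to endothelial-like cells because a bound from an assumed profile excludes nothing. A form that divided each ratio by that of Col1a1 argued against free RNA for all 9 genes, but was dropped because it would do so even for a gene higher in endothelial-like cells, and each gene was judged by its own ratio. Free RNA was taken as argued against only for a ratio over 2 whose interval lay above 1.51, the ratio of median depths of the 2 classes. The test of doublets in brain infarct first used class averages of that library without smooth-muscle-like cells, which argued against doublets. A form that used every other brain cluster of 50 or more cells in a library left them open, with 16 of 163 list genes at least 1.5 times above each, fewer than the 10% its prediction named. The test given, chosen last and with those outcomes known, is the share of cells with both Y-linked and Xist UMIs, set against 0.5 times the lowest share that doublets of 2 named classes of the library would give. Tables were handled with pandas 2.3.3, nearest neighbours with scikit-learn 1.9.0 and plots with matplotlib 3.10.9.

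The procedure was tested on simulated data, in which 200 genes of a library were given known ratios. All genes set 4-fold or 8-fold apart were recovered in each of the 6 comparisons, as were between 38.7% and 55.6% of those set 2-fold apart, which lie at the threshold. None of the unchanged genes was counted. Simulated counts varied by counting error alone around the same profile, so these rates do not cover differences between animals or libraries. Of 100 lists without a set difference, 3 fell outside percentiles 2.5 to 97.5. These held random genes in simulated counts of brain sham alone, unlike lists compared between libraries. A free RNA share set to 30% was found as 30.1%, with the fibroblast markers silent in the receiving cells by design.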

Results

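Single-cell RNA counts were collected from cells of adult mice in which tamoxifen, given for 4 days, switched on the red fluorescent protein tdTomato in cells expressing Tbx18, a transcription factor of mural cells (pericytes and vascular smooth muscle). Cells sorted for tdTomato came from the ventricles of the heart after ligation of the left anterior descending coronary artery or sham surgery, and from the cerebral cortex after photothrombotic stroke or sham surgery. Each organ gave 3 libraries, from sham tissue, infarcted tissue and the tissue around the infarct, so the 6 groups hold 1 library each and no difference below has a replicate check. The labels give neither the time after injury nor the number of animals per library. The series title raises the question whether pericytes show a parallel fibrotic response in both organs. The heart libraries held 17951 barcodes for sham, 9470 for infarct and 9580 for peri-infarct, with 32194158, 107892408 and 95248788 UMIs (unique molecules). The brain libraries held 2808, 2368 and 2589 barcodes in the same order, with 12311632, 54810989 and 11796570 UMIs. After filtering, the median depth per cell was 1387 UMIs in heart sham against 10466.5 in heart infarct and 8579 in heart peri-infarct. In brain it was 3331 in sham, 25920.5 in infarct and 2911.5 in peri-infarct. Malat1, a nuclear RNA, took 7.23% of the UMIs in heart sham against 2.25% and 2.48% in the heart injury libraries. Its share was 5.25% in brain sham, 0.743% in brain infarct and 2.73% in brain peri-infarct.

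The sorted cells were of several kinds. In heart, fibroblast-like cells made up 41.4% of sham, 60.1% of infarct and 60.3% of peri-infarct cells, all shares depending on the tdTomato gate and on depths that differ between libraries. With doublet calls kept, the fibroblast-like shares were 29.6%, 14.5% and 47.6%, and 54.1% of heart infarct cells were unnamed. Smooth-muscle-like cells made up 29.1% of heart sham (exact Clopper-Pearson 95% interval 28.2% to 29.9%), 7.16% of infarct and 6.02% of peri-infarct. Pericyte-like cells numbered 48 in heart sham, a share of 0.415%, against 1101 in infarct (13.8%) and 585 in peri-infarct (8.02%). In brain, pericyte-like cells made up 52.0% of sham (50.03% to 53.9%), 20.7% of infarct (18.9% to 22.5%) and 43.8% of peri-infarct cells. Clusters that matched no class were kept out of the classes. They held 3.72% of heart sham, 7.60% of heart infarct, 1.54% of heart peri-infarct, 8.70% of brain sham, 52.1% of brain infarct and 17.1% of brain peri-infarct cells. Intervals cover counting error only. Because heart sham had fewer than 50 pericyte-like cells, the comparisons with heart sham sum pericyte-like and smooth-muscle-like cells together, named mural cells here. Smooth-muscle-like cells were 3363 of the 3411 mural cells in heart sham but 573 of 1674 in infarct and 439 of 1024 in peri-infarct. A cluster that held 98.2% of the smooth-muscle-like cells of heart sham held 1.40% of those of infarct, where another cluster held 91.3%. The smooth muscle gene Myh11 was also among the leading genes of mostly-sham clusters named fibroblast, endothelial, mesothelial or epicardial, and macrophage or monocyte. Rgs5, which led the pericyte-like heart clusters, was among those of the sham smooth-muscle-like cluster. Whether free RNA placed sham pericytes in the smooth-muscle-like class was not tested.

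Mural cells of the infarcted heart carried more matrix transcripts than mural cells of sham heart. Fibronectin (Fn1), periostin (Postn), and collagens III, V and VI stood higher, together with the basement membrane chains Col4a1 and Col4a2. Prc1, Cenpa and Stmn1, genes linked to cell division, were also higher, although the cell cycle list had too few tested members for a median. Immediate early genes such as Atf3, Klf4 and Egr1 stood lower, and so did a set of fibroblast transcripts led by Clec3b and Dcn. Of 3026 genes with a mean of at least 50 CPM (counts scaled to a total of 1000000), 231 were at least 2-fold higher and 217 at least 2-fold lower. The higher count was 136 in smooth-muscle-like cells alone and 387 with free RNA subtracted, and the lower count 380 with pericyte-like cells alone. Fn1 (ENSMUSG00000026193, mm10 chromosome 1, 71585520 to 71653200) stood at 844 CPM against 104, a log2 ratio of 3.01 (fold 8.07, Poisson interval of the ratio 7.50 to 8.84). Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037) stood at 683 against 117 CPM, a log2 ratio of 2.54. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) stood at 1990.0 against 735 CPM (1.44), and Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) at 849 against 422 (1.01). Among other collagens, log2 ratios were 2.40 for Col6a3, 2.04 for Col5a2, 1.40 for Col5a1, 2.18 for Col4a1, 2.36 for Col4a2 and 1.96 for Col18a1. Of 10 tested collagen processing genes 5 were higher, among them Loxl2 (2.16), Serpinh1 (1.59) and Bmp1 (1.80). Matrix proteases and inhibitors went both ways, with 5 of 12 higher, among them Mmp14 (2.11), Mmp11 (2.89) and Adamts12 (2.53), and 3 lower, Adamts1 (455 against 997 CPM), Timp3 (192 against 521) and Adamts5 (41.9 against 154). The cell-division gene Prc1 stood at 100.1 against 1.52 CPM, resting on 9 UMIs in sham, and its log2 ratio of 5.33 became 1.90 with doublet calls kept. Mki67, below the CPM filter, stood at 84.9 against 1.18 CPM on 7 sham UMIs. Other genes with the highest ratios were Rgs16 (4.21), Thy1 (3.61), Acan (3.51), Tmem176a (3.34), C1qtnf6 (3.29) and Ctsc (3.04). The lipid-binding gene Fabp5 stood at 1356 against 183 CPM, the protease inhibitor Serpine2 at 913 against 121, and the endothelin receptor Ednrb at 105 against 12.5. Acta2, the smooth muscle actin, was near even in the summed mural cells, at 7776 against 7718 CPM. Myh11 was lower at -1.51 and Tbx18 was near even at 0.16. Acta2 stood at 5273 CPM in the pericyte-like cells of the infarct alone. Because the mix of mural cells differs from sham, an even sum does not show that either class was even. The lowest ratios were those of Clec3b (-5.57), Pcolce2 (-5.18), Smoc2 (-4.93), Pdgfra (-4.84), Dpep1 (-4.71) and Dcn (-4.17). In heart sham Dcn was also high in endothelial-like cells, at 3434 CPM against 4189 in mural cells.

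Several of these matrix genes stood higher in the pericyte-like than in the smooth-muscle-like part of the heart infarct library. In pericyte-like cells of the infarct Col1a1 stood at 1210.0 CPM, against 123 in smooth-muscle-like and 127 in endothelial-like cells of the same library. Postn stood at 961, 123 and 83.3 CPM in the same 3 classes, and Col3a1 at 2783, 394 and 390. Fn1 was high in smooth-muscle-like cells as well, at 918, 697 and 277 CPM. In heart sham, Col1a1 in the 48 pericyte-like cells (302 CPM) equalled that in endothelial-like cells (300.3). With smooth-muscle-like cells alone, Col1a1 was lower in infarct than in sham at -1.78 and Col3a1 at -0.89. In sham these cells held 86.4% of 22 fibroblast markers and fibrillar collagens within 1.5-fold of endothelial-like cells. The estimated free RNA share was 43.8% in sham and 3.49% in infarct, so the lower values need not be a change in the cells. With pericyte-like cells alone the log2 ratios were 2.0 for Col1a1, 1.53 for Col3a1, 1.71 for Postn and 1.64 for Fn1, while Pdgfrb (-0.39), Kcnj8 (-1.61) and Abcc9 (-1.37) turned lower. A Col1a1 UMI was seen in 46.8% of 1100 infarct pericyte-like cells thinned to 1000 UMIs (1 cell left out, 78.2% unthinned). The share was 8.92% of thinned endothelial-like cells, with median depths of 4436 and 5285 UMIs. In sham it was 20.8% of the 48 pericyte-like cells (33.3% unthinned) and 25.5% of endothelial-like cells, with depths of 2560.5 and 1385. The sham share was thus no higher than in endothelial-like cells. Whether it is free RNA or expression of these cells is not settled. Only 36.4% of the 22 fibroblast markers and collagens lay within 1.5-fold of endothelial-like cells in these 48 cells. A Postn UMI was seen in 49.5% of thinned infarct pericyte-like cells (83.6% unthinned) and 7.69% of endothelial-like cells, against 16.7% (35.4% unthinned) and 7.11% in sham. A Mki67 UMI was seen in 3.64% of thinned infarct pericyte-like cells (10.4% unthinned) and 1.23% of endothelial-like cells, and in 0 of the 48 sham cells, which allows up to 7.40%.

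Across the fixed lists, the heart infarct mural cells had median log2 ratios of 1.21 for fibrillar collagens (9 of 11 tested members at least 2-fold higher) and 1.08 for collagen processing (5 of 10). Both medians lay at percentile 100 of 10000 random lists matched on mean expression, a description of these libraries and not a test. The matrix proteases and inhibitors list had a median of 0.59 (percentile 98.7) and the angiogenic and pericyte-endothelial signalling list 0.74 (99.3). The matrix glycoproteins list went both ways, with 4 of 16 members higher, 5 lower and a median of 0.44. Of the 3 matrix lists together (fibrillar collagens, matrix glycoproteins and collagen processing), 18 of 37 tested genes were at least 2-fold higher and 5 lower. These medians depend on the mix of mural cells: with smooth-muscle-like cells alone they were -0.65 for fibrillar collagens, -0.23 for matrix proteases and inhibitors and 0.38 for the contractile list, and 4 matrix genes were higher. Collagens in sham smooth-muscle-like cells lie near the endothelial-like level, as free RNA would give, so the -0.65 need not be a fall in these cells. The angiogenic and pericyte-endothelial signalling list stood at -0.18 with pericyte-like cells alone. The dissociation stress list was lower at -1.32 (13 of 20 lower, percentile 0.0) and the contractile list at -0.37 (percentile 0.330). Medians inside the random range were 0.26 for basement membrane, 0.51 for TGF-beta signalling, 0.44 for vasoactive receptors and channels, 0.71 for integrins and adhesion and 0.48 for interferon response. The same held for cytokines and inflammation (0.22), complement (0.42), glycolysis and hypoxia (0.43), oxidative phosphorylation (-0.02) and endoplasmic reticulum stress and secretion (0.39). Fewer than 3 members were tested of the cell cycle (2), osteochondral (1), adipogenic (2) and neural progenitor (2) lists.

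**Figure D1:**
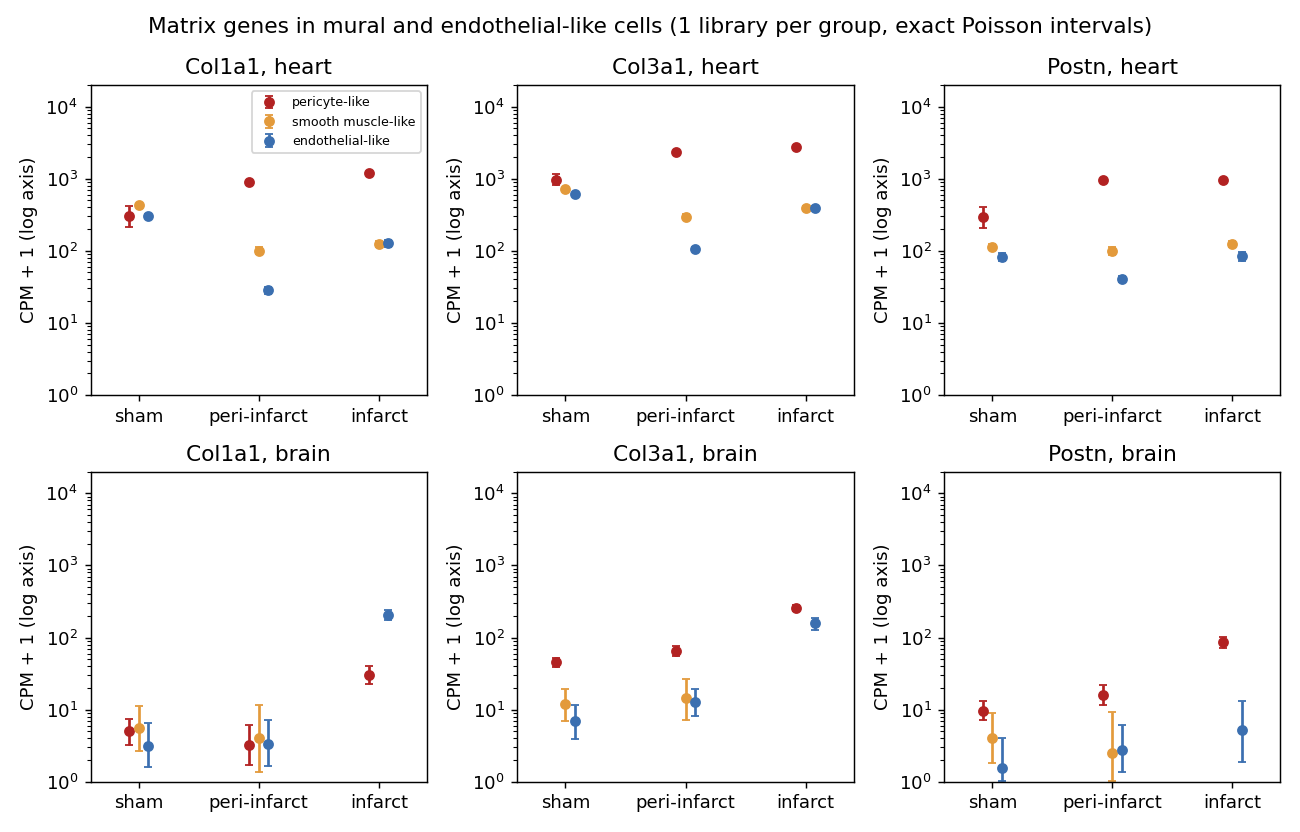
CPM (log axis) of Col1a1, Col3a1 and Postn in pericyte-like, smooth-muscle-like and endothelial-like cells of each library, where a class holds at least 20 cells. Exact Poisson 95% intervals cover counting error only. In brain pericyte-like cells, Col3a1 stands at 256 CPM in infarct against 44.3 in sham, and Col1a1 at 29.6 CPM against 3.98. In brain infarct the ratio of pericyte-like to endothelial-like cells is 1.64 for Col3a1 and 0.144 for Col1a1.

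Mural cells around the heart infarct, summed as above, also stood above sham in matrix genes, with smaller collagen ratios than in the infarct, but smooth-muscle-like cells alone did not. Postn, Fn1, Col4a1 (1.80) and Col4a2 (1.89) were higher, as were the pericyte genes Higd1b and Colec11. With pericyte-like cells alone, Colec11 stood at 0.04. The highest ratio was that of haptoglobin, Hp, with 710 UMIs against 0 in sham, at least 218-fold higher against a floor of 3 sham counts. Of 37 tested matrix genes 12 were at least 2-fold higher and 5 lower, all of the lower ones matrix glycoproteins, where 6 of 17 were higher. Of all 3047 genes tested, 163 were at least 2-fold higher and 169 lower. The higher count was 73 with up to 20% mitochondrial UMIs, 107 with TMM factors, 80 in smooth-muscle-like cells and 289 with free RNA subtracted, and the lower count 293 with pericyte-like cells alone. The count of higher matrix genes was 19 with free RNA subtracted and 21 with at least 200 or at least 1000 genes per cell. Postn stood at 599 against 117 CPM (2.35), Fn1 at 484 against 104 (2.21), Col3a1 at 1503 against 735 (1.03) and Col1a1 at 564 against 422 (0.42). With pericyte-like cells alone Col1a1 stood at 1.56, Postn at 1.69, Fn1 at 1.27 and Col3a1 at 1.28, and Nov, Kcnj8 and Abcc9 took the opposite sign to the mural cells. With smooth-muscle-like cells alone 0 matrix genes were at least 2-fold higher, Col3a1 stood at -1.30 and Postn at -0.19, and the medians were -1.30 for fibrillar collagens, -0.55 for matrix glycoproteins and -0.02 for collagen processing. Their sham collagen level lies near that of endothelial-like cells, as free RNA would give, so these values do not settle whether the cells changed. Also higher were Thy1 (3.05), Tmem176a (2.96), Fabp5 (2.68), Nov (2.67), Colec11 (2.62), Higd1b (2.57), Ctsc (2.55), Arhgdib (2.46), Stmn1 (2.36) and Il34 (2.25). Acta2 (0.17) and Tbx18 (0.49) were less than 2-fold apart, and Mki67 stood at 47.5 against 1.18 CPM. The lowest ratios were those of Igfbp6 (-5.50), Pi16 (-5.25), Smoc2 (-4.90), Pdgfra (-4.24), Clec3b (-4.16) and Fbln2 (-3.90), again fibroblast transcripts. Fibrillar collagens had a median of 0.75 (percentile 99.96), collagen processing 0.76 (99.9), matrix glycoproteins 0.64 (99.99), vasoactive receptors and channels 0.81 (99.9) and integrins and adhesion 0.76 (99.7). Dissociation stress (-1.03, percentile 0.0), matrix proteases and inhibitors (-0.56, 0.330), TGF-beta signalling (-0.40, 0.320) and the contractile list (-0.16, 1.64) lay low. Of these 4 lists only dissociation stress kept its sign in every setting. Matrix proteases and inhibitors stood at 0.67 with pericyte-like cells alone, 0.33 with free RNA subtracted and 0.15 with doublet calls kept. TGF-beta signalling stood at 0.03 with smooth-muscle-like cells alone and 0.04 with doublet calls kept, and the contractile list at 0.50 and 0.10 in the same settings. The vasoactive list stood at -0.72 with pericyte-like cells alone. No other list left the random range.

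Within the injured heart, pericyte-like cells of the infarct and of its surroundings were close. The comparison asks which transcripts mark the infarct itself. Postn (0.02), Col3a1 (0.24), Fn1 (0.37) and Col1a1 (0.44) were all less than 2-fold apart. Of 3173 genes tested, 8 were at least 2-fold higher in the infarct and 19 lower, a balance that turned in other settings. It was 40 higher and 5 lower with each library clustered on its own, 27 and 7 with at least 1000 genes per cell, 15 and 5 with the response genes left out of the clustering, and 15 and 10 in smooth-muscle-like cells. Timp1 stood at 160.4 against 49.1 CPM (1.69) and Pgf at 92.0 against 44.9 (1.02). The cell cycle list had a median of 0.58 (percentile 100), with Birc5 at 1.11, Ube2c at 1.09, Top2a at 0.71 and Mki67 at 0.64. Cytokines and inflammation (0.61, percentile 99.99) lay high, with Il6 at 0.89, Ccl2 at 0.83 and Cxcl1 at 0.67. Cxcl12 of that list went the other way (-0.63), and 0 of its 7 tested members were at least 2-fold apart. Fibrillar collagens (0.33) and dissociation stress (0.29) lay at percentile 100, and TGF-beta signalling (0.31), matrix proteases and inhibitors (0.20) and collagen processing (0.18) above 97.5. The vasoactive list (-0.28, percentile 0.0500) and the contractile list (-0.17, 0.0600) lay low. With each library clustered on its own the vasoactive list stood at 0.03, the contractile list at 0.41 and collagen processing at -0.16. Dissociation stress stood at -0.28 with pericyte-like and smooth-muscle-like cells together. Over all cells the cell cycle list stood at -0.30. Eln, Fbln1 and Wisp2 were lower, at -1.34, -2.62 and -2.14, but took the opposite sign when each library was clustered on its own (1.37, 0.36 and 2.34).

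Pericyte-like cells of the infarcted cortex, 420 cells against 1344 in sham, carried more transcripts of matrix, of interferon response and of chemokines. The chemokines Ccl2, Cxcl10 and Cxcl1 and the interferon-induced genes Isg15, Ifit3 and Ifi27l2a were among those furthest above sham. Fn1, Col3a1, Dcn, Col5a3, Col18a1 and the procollagen protease Bmp1 were among the matrix genes. The intermediate filament genes Vim and Gfap and the lipid-binding genes Fabp7 and Fabp5 were higher as well. Of 3920 genes tested, 164 were at least 2-fold higher and 114 lower, and 9 of 23 matrix genes were higher. In male cells alone 188 were lower, and by the mean of each cell's own CPM 103 were higher and 70 lower. Fn1 stood at 466 against 74.6 CPM (2.63, ratio interval 5.44 to 7.17), Col3a1 at 256 against 44.3 (2.50), Dcn at 265 against 40.3 (2.68) and Col5a3 at 219 against 47.3 (2.19). Fn1 was higher in endothelial-like cells of the infarct library, at 874 CPM, than in its pericyte-like cells. Further matrix ratios were 2.38 for Bmp1, 4.05 for Col18a1, 4.29 for Mmp11, 1.64 for Cyr61, 1.56 for Col5a2, 1.32 for Col4a1 and 1.16 for Pcolce. Postn (84.8 against 8.71 CPM, 3.14) and Col1a1 (29.6 against 3.98, 2.62) were below the CPM filter. Col1a1 likewise stood at 206 CPM in endothelial-like cells of the infarct. Gfap had 332 UMIs against 0 in sham, at least 299-fold higher against a floor of 3 sham counts, and stood at 223 CPM against 43.1 in endothelial-like cells. Gfap and Fabp7 are best known from astrocytes. A pericyte-like cluster with Slc1a2 and Mt3, also known from astrocytes, among its leading genes held 10.5% of the infarct and 8.56% of the sham pericyte-like cells, and whether Gfap and Fabp7 come from RNA of astrocytes was not tested. Cxcl10 had 174 UMIs against 2, with a ratio interval of 64.2 to 1959. Ccl2 stood at 168 against 3.98 CPM (5.09), Isg15 at 289 against 22.4 (3.63), Spp1 at 187 against 5.72 (4.81), Fabp7 at 279 against 8.46 (4.89) and Vim at 1367 against 128 (3.41). Spp1 stood at 160 CPM in endothelial-like and 35200.0 in macrophage-like cells of the infarct library. Serpine2 (2.95), S100a6 (3.89), Ifi27l2a (5.73), Cxcl1 (3.34), Ifit3 (3.27), Fabp5 (3.38) and Socs3 (2.66) were also higher. Pdgfrb (-0.15) and Tbx18 (-0.58) were less than 2-fold apart. The contractile genes Acta2 (2.88) and Tagln (1.32) took the opposite sign in several settings, -0.20 and -1.46 when the response genes were left out of the clustering. Ptgds (-7.15) was lowest, and other low ratios were those of Rapgef4 (-2.64), Pde10a (-2.01), Malat1 (-1.87) and Srebf2 (-1.76). Ptgds also led several fibroblast-like clusters of the brain, and whether its level in sham pericyte-like cells came from free RNA was not tested. Xist, the RNA of the inactive X chromosome, had 663 UMIs against 1. Brain sham held 1631 cells with Y-linked UMIs alone and 2 with Xist alone, and brain infarct held 573 and 1180, so sex differs along with surgery. A cluster with 55.2% of the infarct pericyte-like cells held 0 of the sham ones, where the fullest cluster held 43.8%.

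Lists in brain infarct pericyte-like cells lay furthest from the random range for interferon response (median 2.44, 5 of 6 tested higher), cytokines and inflammation (2.06, 3 of 6) and fibrillar collagens (1.87, 3 of 4), each at percentile 100. Dissociation stress was higher at 1.30 (13 of 20, percentile 100), opposite in sign to the heart mural cells. These classes are unlike, so the signs alone do not set the organs apart. Over all cells of the library cytokines and inflammation stood at -0.40, dissociation stress at -0.59 and basement membrane at -0.62. Matrix glycoproteins (0.49, percentile 98.8), basement membrane (0.45, 99.1) and collagen processing (0.29, 98.9) also lay high. Inside the random range were matrix proteases and inhibitors (0.42), contractile (-0.11), TGF-beta signalling (-0.08), angiogenic and pericyte-endothelial signalling (-0.15), vasoactive receptors and channels (-0.26) and integrins and adhesion (0.00). Glycolysis and hypoxia (0.31), oxidative phosphorylation (0.16) and endoplasmic reticulum stress and secretion (-0.06) lay there too. The complement list had 2 tested members, too few for a median, and the neural progenitor list 2, Vim and Nes (-0.32). Cell cycle and osteochondral had 1 each and adipogenic 0. A Col3a1 UMI was seen in 18.3% of 394 thinned infarct pericyte-like cells (26 left out, 36.9% unthinned) and 3.32% of 1324 sham cells (20 left out, 9.75% unthinned). The endothelial-like shares were 3.00% and 1.23%, with median depths of 2935.5 and 2725 UMIs in pericyte-like and 4442 and 3693.5 in endothelial-like cells. For Postn the pericyte-like shares were 5.33% in infarct and 0.755% in sham (13.1% and 2.38% unthinned), with 0 of 100 infarct endothelial-like cells, which allows up to 3.62%. A Tbx18 UMI was seen in 9.64% of infarct and 12.8% of sham pericyte-like cells (25.0% and 29.99% unthinned), against 0 and 0.985% of endothelial-like cells.

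**Figure D2:**
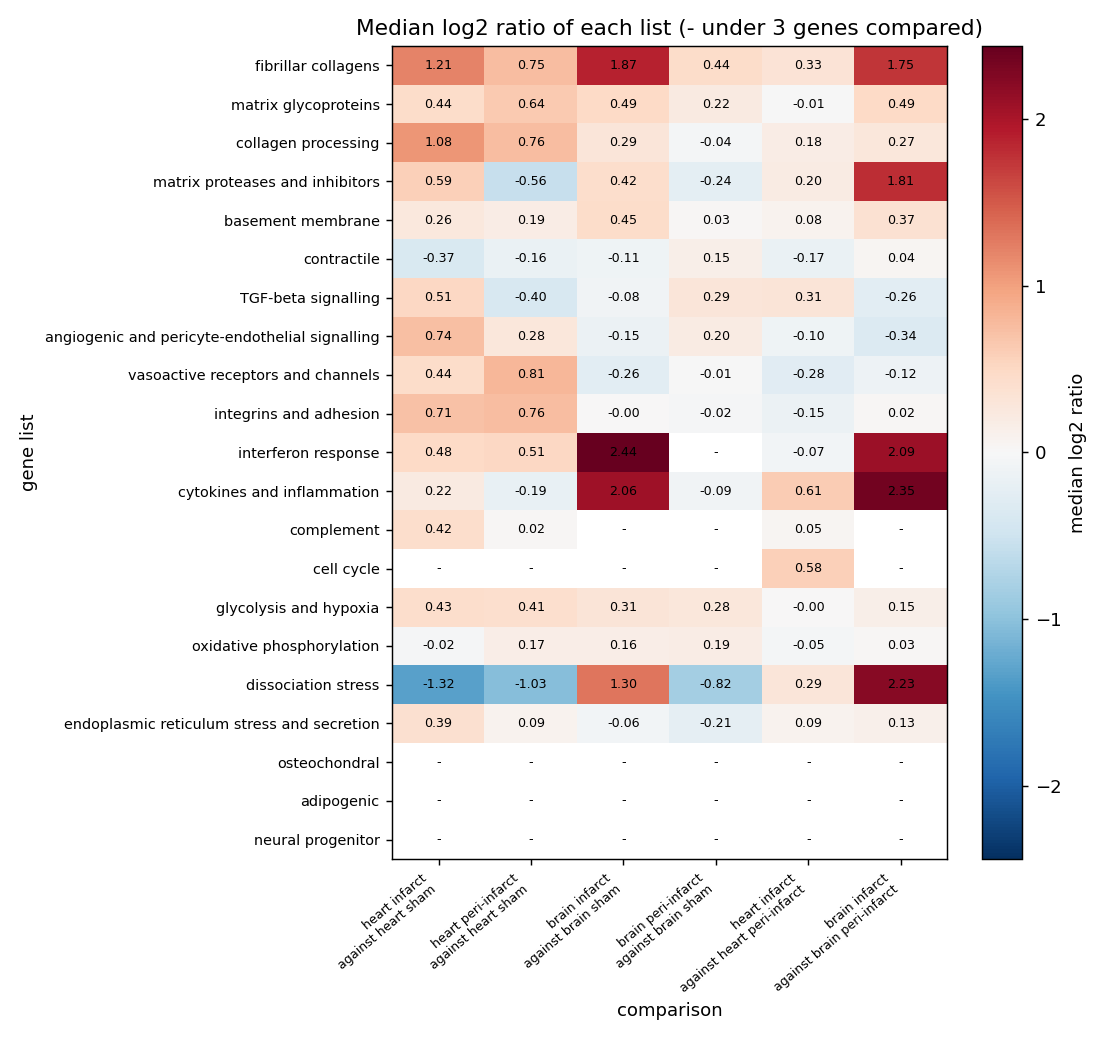
Median log2 ratio of each fixed gene list in the 6 comparisons, in mural cells where heart is set against sham and in pericyte-like cells elsewhere. The interferon response median is 2.44 in brain infarct pericyte-like cells and 0.48 in heart infarct mural cells. These classes are unlike, so the values alone do not set the organs apart.

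Around the cortical infarct, pericyte-like cells stood near sham. No matrix gene of the 17 tested was at least 2-fold higher, and stress genes were lower. Of 3954 genes tested, 6 were at least 2-fold higher and 25 lower. Sex differs along with surgery here too: in male cells alone 14 genes were higher and 52 lower, 1 of the higher ones a matrix gene. In smooth-muscle-like cells 19 genes were higher, 1 of them a matrix gene. The 6 included Xist (1392 UMIs against 1), AY036118 (2.25), Lars2 (1.47) and the histone genes Hist1h1e (1.83) and Hist1h4d (1.40). Hspa1b (-2.57), Hspa1a (-2.33), Jun (-2.22), Fosb (-1.87), Adamts1 (-1.68), Fos (-1.58), Dnajb1 (-1.53) and Egr1 (-1.41) were lower. Among smooth-muscle-like cells Jun, Fos, Dnajb1 and Egr1 were not lower, at 0.09, 0.48, 0.55 and 0.14. Ptgds (-1.52, but 2.05 with up to 20% mitochondrial UMIs per cell), Pde10a (-1.54), the Y-linked Ddx3y (-1.48) and Malat1 (-1.01) were lower as well. Col3a1 (0.54), Fn1 (0.33), Mgp (0.85), Cthrc1 (0.60), Pdgfrb (0.15) and Tbx18 (-0.37) were less than 2-fold apart. Col1a1 stood at 2.21 against 3.98 CPM, Postn at 15.01 against 8.71 and Acta2 at 37.5 against 26.4. The dissociation stress list had a median of -0.82 (6 of 17 lower, percentile 0.0), fibrillar collagens 0.44 (percentile 99.3), TGF-beta signalling 0.29 (99.3) and glycolysis and hypoxia 0.28 (98.2). In smooth-muscle-like cells dissociation stress stood at 0.18 and TGF-beta signalling at -0.29, and over all cells glycolysis and hypoxia stood at -0.12. The remaining lists lay within the random range or had fewer than 3 tested members.

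Set against those of its own surroundings, pericyte-like cells of the cortical infarct were again higher in matrix and inflammatory genes. Both libraries mix male and female cells, but in unlike shares. Pericyte-like cells with Y-linked and with Xist UMIs alone numbered 135 and 151 in infarct, and 188 and 462 in peri-infarct. The cells compared sit largely in different clusters. A cluster with 55.2% of the infarct cells held 2.99% of the peri-infarct ones, and another held 13.6% and 49.55%. Of 3842 genes tested, 130 were at least 2-fold higher in the infarct and 40 lower, with 8 of 22 matrix genes higher. Fn1 stood at 466 against 94.1 CPM (2.30), Col3a1 at 256 against 64.9 (1.96), Dcn at 265 against 49.0 (2.41), Cyr61 at 171 against 23.0 (2.84) and Timp1 at 98.2 against 3.97 (4.32). Cxcl10 had 174 UMIs against 3, with a ratio interval of 29.8 to 433. Ccl2 (3.98), Cxcl1 (3.68), Ifi27l2a (4.72), Isg15 (2.80), Irf7 (2.09), Spp1 (3.81), Vim (3.05), Col18a1 (2.65), Mmp11 (2.87) and Bmp1 (1.99) were higher. With up to 20% mitochondrial UMIs per cell, Cxcl10 (-0.22), Ccl2 (-1.19) and the cytokines and inflammation list (-0.08) took the opposite sign here. Over all cells so did that list (-0.76), Cxcl10 (-1.57), Ccl2 (-0.78), Isg15 (-0.15), Irf7 (-1.36) and Cyr61 (-0.36). Dissociation stress genes had a median of 2.23 (17 of 20 higher), with Atf3 at 4.17, Jun at 3.53, Klf2 at 3.43 and Fosb at 3.36. With both mural classes summed Atf3 stood at -1.21 and Klf2 at -0.69, and over all cells they stood at -1.43 and -1.28 and the dissociation stress list at -0.28. List medians were 2.35 for cytokines and inflammation (0.99 in male cells alone), 2.09 for interferon response, 1.81 for matrix proteases and inhibitors and 1.75 for fibrillar collagens. Jag1 (-0.78), Anpep (-0.83) and Abcc9 (-0.62) were lower by less than 2-fold.

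Heart and brain infarct had higher genes in common. Of 2630 genes tested in both organs, 187 were at least 2-fold higher in heart mural and 138 in brain pericyte-like cells, and 41 were higher in both, against 9.81 for independent lists. The 41 became 19 with smooth-muscle-like heart cells alone, 64 with free RNA subtracted and 111 over all cells. The overlap of independent lists was not computed for those settings. Heart mural cells differ in mix from sham, so the excess over 9.81 need not be a shared response of pericytes. The shared genes with the largest smaller ratio included Fn1 (3.01 in heart, 2.63 in brain), Serpine2 (2.91 and 2.95), Fabp5 (2.88 and 3.38), Rgs16 (4.21 and 2.77) and Mmp11 (2.89 and 4.29). Tmem176a (3.34 and 3.84), Tmem176b (2.30 and 3.35), Ctsc (3.04 and 2.37), Lgals1 (2.03 and 2.12) and Col18a1 (1.96 and 4.05) completed them. In brain infarct Fn1 stood at 874 CPM in endothelial-like against 466 in pericyte-like cells, and the others were not tested for free RNA. Lower in both were 12 genes, against 1.86 for independent lists, among them Malat1 (-1.48 and -1.87), Zrsr1 (-2.24 and -1.41), Abca8a (-2.74 and -1.03), Cwc22 (-1.95 and -1.16), Spry2 (-1.65 and -1.20) and Nrd1 (-1.37 and -1.35). The 12 moved by over 1.5 times in other settings, up in some and down in others, as printed below. Isg15 stood at 0.37 in heart and 3.63 in brain, and Atf3 at -2.63 and 1.81, differences that were not tested. With pericyte-like cells alone, 48 of them in sham, Isg15 stood at 3.05 in heart, and with both mural classes summed Atf3 stood at -0.59 in brain. Around the infarct 0 genes were higher in both organs and 4 were lower, against 0.391 for independent lists, namely Egr1, Fos, Jun and Malat1. With male brain cells alone 3 were higher and 9 lower in both, over all cells 5 and 7, and with up to 20% mitochondrial UMIs or with smooth-muscle-like heart cells alone 1 was lower.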

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

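All tests in this part were chosen after the results were seen. Among the list medians and the 8 genes always named, 3 results come first in which both injury libraries of heart pointed one way and both of brain the other, none of them tested, since each group is 1 library. Other genes were not searched for this. A list at 0.00 in a comparison (integrins and adhesion) or opposite in infarct alone is not among them. An example of the latter is dissociation stress (-1.32 in heart mural cells, 1.30 in brain pericyte-like cells). The vasoactive receptors and channels list had a median log2 ratio of 0.44 in heart infarct and 0.81 in heart peri-infarct mural cells, against -0.26 and -0.01 in brain pericyte-like cells. With pericyte-like cells alone the heart medians were -1.06 and -0.72, so the direction in heart depends on which mural cells are summed. Endoplasmic reticulum stress and secretion genes had medians of 0.39 and 0.09 in heart against -0.06 and -0.21 in brain, all inside the range of random lists. Tbx18 stood at 0.16 and 0.49 in heart against -0.58 and -0.37 in brain, and with pericyte-like cells alone at -1.33 and -0.86 in heart.

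Fibroblast and collagen transcripts were spread over the mural cells of the heart sham library, and this sets the base of every comparison with heart sham. Of 22 fibroblast markers and fibrillar collagens, 86.4% stood within 1.5-fold of their CPM in endothelial-like cells, as RNA free in the suspension would give; the values are for smooth-muscle-like cells, and were 36.4% in the 48 pericyte-like cells of the same library and 28.0% of 25 genes in smooth-muscle-like cells of heart infarct. Fibroblasts or doublets counted among the mural cells would place these transcripts in a minority of cells, but 84.3% of thinned smooth-muscle-like cells held a Dcn UMI. Dcn was also high in endothelial-like cells of this library, so free RNA alone could place a UMI in most cells. The share therefore cannot decide whether fibroblasts or doublets were counted as well. Free RNA may therefore account for the very low ratios of Clec3b, Pcolce2, Smoc2, Pdgfra and Dcn, and it would hide part of a collagen difference. It may also account for the lower collagen values in smooth-muscle-like cells alone. With free RNA subtracted none of Clec3b, Pcolce2, Smoc2, Pdgfra and Dcn took the opposite sign in heart infarct, while Pcolce2 did around the infarct. Among other named genes, Ifi27l2a took the opposite sign in heart infarct and C3 around the infarct. With free RNA subtracted, Col1a1 in heart infarct moved from 1.01 to 2.08 and Col3a1 from 1.44 to 2.55, and no biological explanation was tested.

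Matrix genes stood higher in brain infarct than in brain sham pericyte-like cells. Free RNA, which reaches all classes alike, stays open for genes no higher than in endothelial-like cells of the library, namely Col1a1 (ratio 0.144) and Fn1 (0.533), and was not decided for Cyr61 (1.13) and Col3a1 (1.64). It is argued against for Col5a2 (3.52), Bmp1 (3.90), Col5a3 (19.7), Pcolce (20.5) and Dcn (27.2), with the lowest interval, that of Col5a2, starting at 2.34. Fkbp10 (2.35, interval from 1.54) passed the same rule, which does not use the sham level. It stood at 88.15 CPM in infarct and 42.5 in sham pericyte-like cells, and at 37.5 in infarct endothelial-like cells. Free RNA at the endothelial-like level could cover most of that rise, so it stays open for Fkbp10. Doublets with collagen-rich cells are argued against by the 9 of 9 genes still at least 2-fold higher in cells without a Col1a1 UMI, and the sex of the animals by the 8 of 9 still so in male cells alone (Fkbp10, at 0.81, is the exception). For Col5a2, Bmp1, Col5a3, Pcolce and Dcn a response of pericytes to infarction may account for the values, as a hypothesis that 1 library each cannot separate from other differences between the libraries.

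In the brain infarct library 3 collagen-rich clusters, closest to the fibroblast markers, stayed unnamed because Acta2, a smooth muscle marker, and no fibroblast marker stood among their leading genes. They held 916 cells (45.1% of the library) against 2 in brain sham and 5 in brain peri-infarct. Cells of a lone animal would carry Y-linked or Xist UMIs of almost 1 kind, but of the cells with UMIs of only 1 kind 17.2% carried Y-linked ones, against 48.0% in the rest of the library. These were 150 cells with Y-linked and 721 with Xist UMIs alone. The test concerns cells that all come from 1 animal, and it leaves open that most came from 1 female. Doublets of other classes would often join both sexes, in at least 22.4% of such cells from the sex-linked UMIs of the named classes, but 1.25% (11 of 882, interval 0.624% to 2.22%) of these cells with Y-linked or Xist UMIs carried both. The naming depends on the clustering, since with each library clustered on its own unnamed cells made up 8.71% of brain infarct, smooth-muscle-like cells 31.0% and fibroblast-like cells 28.9%, and clusters from mostly 1 library may be a property of that library, while a cell state of the infarct was not tested.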

How the results depend on the processing

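Of the 20 alternatives, 15 were chosen before the data were examined, and 5 after: free RNA subtracted, smooth-muscle-like cells only, pericyte-like cells only, male cells only, and barcodes seen in another library left out. Of 8306 recomputed log2 ratios of named genes, 5258 stayed within the counting interval of the reported value, 2906 moved beyond it without a called value changing sign and 142 took the opposite sign. Of 1492 list medians 1366 stayed within 0.5, 87 moved further and 39 took the opposite sign. An opposite sign was counted only for lists outside the random range and for tested genes at least 2-fold apart. Other sign changes were counted by distance alone. Of 371 counts of genes 274 stayed within 1.5 times the reported count. Of 352 shares of cells, 227 stayed within their interval. Leaving out barcodes seen in another library moved 2 named genes and no count or list median. In heart infarct against sham, over the settings other than all cells and smooth-muscle-like cells only, Col3a1 ran from 1.23 to 2.55, Postn from 1.71 to 3.27, Fn1 from 1.64 to 3.35 and Col1a1 from 0.55 to 2.08. In brain infarct against sham, all cells aside, Col3a1 ran from 2.12 to 2.90, Postn from 2.90 to 3.34 and Fn1 from 1.87 to 2.90. Male cells were taken in brain alone, so that counts for both organs set them beside the heart cells of the main analysis, and smooth-muscle-like cells only gave none for brain infarct, which held 7 of them. Depth limits heart sham most, with a median of 1387 UMIs per cell and 48 pericyte-like cells. Of 156 counts in fibroblast-like cells, 106 stayed within 1.5 times. Printed below, by setting, are list medians and named genes counted as taking the opposite sign, and the moved counts and shares in the compared cells. Not printed there are other sign changes, such as those of Tbx18 and the heart infarct vasoactive list with pericyte-like cells alone. Named genes, list medians and fibroblast-like counts that only moved are in the totals above. Except for the CPM filters, which change the number of genes tested, the cause was not tested.

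Taking all cells of a library moved the most results. 482 genes were higher in brain infarct against sham, 53 in brain peri-infarct against sham, 34 in heart infarct against peri-infarct, 348 in brain infarct against peri-infarct, 111 in both organs infarct and 5 in both organs peri-infarct. 991 genes were lower in brain infarct against sham, 50 in brain peri-infarct against sham, 57 in heart infarct against peri-infarct, 629 in brain infarct against peri-infarct, 127 in both organs infarct and 7 in both organs peri-infarct. 38 matrix genes were higher in heart infarct against sham, 31 in heart peri-infarct against sham, 32 in brain infarct against sham and 1 in brain peri-infarct against sham. Heart infarct against sham had a list median of angiogenic and pericyte-endothelial signalling -0.60. Heart peri-infarct against sham had list medians of matrix proteases and inhibitors 0.51, TGF-beta signalling 0.06 and vasoactive receptors and channels -1.07. Brain infarct against sham had list medians of basement membrane -0.62, cytokines and inflammation -0.40 and dissociation stress -0.59. Brain peri-infarct against sham had a list median of glycolysis and hypoxia -0.12. Heart infarct against peri-infarct had list medians of contractile 0.18, cell cycle -0.30 and dissociation stress -0.27. Brain infarct against peri-infarct had list medians of cytokines and inflammation -0.76 and dissociation stress -0.28. Lum stood at 0.27, Notch3 at -0.56, Ednrb at -0.12, Abcc9 at -1.08, Ednra at -0.27, Kcnj8 at -1.30, Itga1 at -0.23, Ifi27l2a at 0.19 and C3 at 0.62 in heart infarct against sham. Ndufa4 stood at 0.10 and Fabp4 at -1.57 in heart infarct against sham. Colec11 stood at -0.16, Pi16 at 0.36, Ly6a at 0.21, Fbln2 at 0.78, Cd34 at 0.47, Pdgfrb at -0.32, Vcan at 1.12, Lum at 0.32 and Mmp2 at 0.72 in heart peri-infarct against sham. Actg2 stood at -0.40, Notch3 at -0.76, Abcc9 at -0.77, Kcnj8 at -0.99, Ednra at -0.89, Ifi27l2a at 0.55 and C3 at 0.72 in heart peri-infarct against sham. Acta2 stood at -0.63, Cyr61 at -0.55, Des at -2.91, Tagln at -1.20, Ifit3 at -1.02, Klf2 at -1.30, Junb at -0.23 and Atf3 at -1.36 in brain infarct against sham. Fos stood at 0.01 and Ptgds at 0.34 in brain peri-infarct against sham. Wisp2 stood at 1.83, Eln at 1.34, Cnn1 at 0.35, Pgf at -0.61, Birc5 at -0.09 and Ube2c at -0.15 in heart infarct against peri-infarct. Cyr61 stood at -0.36, Adamts1 at -0.45, Des at -2.20, Tagln at -0.57, Isg15 at -0.15, Ifit3 at -1.21, Irf7 at -1.36, Cxcl10 at -1.57 and Ccl2 at -0.78 in brain infarct against peri-infarct. Nfkbia stood at -0.74, Serping1 at -0.25, Atf3 at -1.43 and Klf2 at -1.28 in brain infarct against peri-infarct.

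Smooth-muscle-like cells only, where both libraries held 50 or more, moved the next largest number. 136 genes were higher in heart infarct against sham, 80 in heart peri-infarct against sham, 19 in brain peri-infarct against sham, 15 in heart infarct against peri-infarct and 19 in both organs infarct. 10 genes were lower in heart infarct against peri-infarct and 1 in both organs peri-infarct. 4 matrix genes were higher in heart infarct against sham, 0 in heart peri-infarct against sham and 1 in brain peri-infarct against sham. Heart infarct against sham had list medians of fibrillar collagens -0.65, matrix proteases and inhibitors -0.23 and contractile 0.38. Heart peri-infarct against sham had list medians of fibrillar collagens -1.30, matrix glycoproteins -0.55, collagen processing -0.02, contractile 0.50 and TGF-beta signalling 0.03. Brain peri-infarct against sham had list medians of TGF-beta signalling -0.29 and dissociation stress 0.18. Heart infarct against peri-infarct had a list median of dissociation stress -0.40. Col1a1 stood at -1.78, Col3a1 at -0.89, Col5a1 at -0.61, Abcc9 at -0.27, Kcnj8 at -1.10 and Hmgb2 at -0.43 in heart infarct against sham. Colec11 stood at -0.39, Stmn1 at -0.08, Col3a1 at -1.30, Postn at -0.19, Col6a3 at -0.35, Col5a2 at -0.85, Loxl2 at -0.38, Adamts2 at -0.03 and Myh11 at 0.06 in heart peri-infarct against sham. Abcc9 stood at -0.91 and Kcnj8 at -1.72 in heart peri-infarct against sham. Jun stood at 0.09, Fos at 0.48, Dnajb1 at 0.55, Ptgds at 1.86 and Egr1 at 0.14 in brain peri-infarct against sham. Cnn1 stood at 0.26 and Ube2c at -0.45 in heart infarct against peri-infarct.

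Without a filter on CPM more genes were tested and counts were larger. 1200 genes were higher in heart infarct against sham, 957 in heart peri-infarct against sham, 1397 in brain infarct against sham, 303 in brain peri-infarct against sham, 141 in heart infarct against peri-infarct and 1332 in brain infarct against peri-infarct. 331 genes were higher in both organs infarct and 37 in both organs peri-infarct. 1248 genes were lower in heart infarct against sham, 982 in heart peri-infarct against sham, 834 in brain infarct against sham, 319 in brain peri-infarct against sham, 266 in heart infarct against peri-infarct and 685 in brain infarct against peri-infarct. 114 genes were lower in both organs infarct and 48 in both organs peri-infarct. 27 matrix genes were higher in brain infarct against sham.

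With a mean CPM of at least 10 more genes were tested too. 660 genes were higher in heart infarct against sham, 442 in heart peri-infarct against sham, 424 in brain infarct against sham, 40 in brain peri-infarct against sham, 36 in heart infarct against peri-infarct and 344 in brain infarct against peri-infarct. 106 genes were higher in both organs infarct and 5 in both organs peri-infarct. 526 genes were lower in heart infarct against sham, 400 in heart peri-infarct against sham, 349 in brain infarct against sham, 72 in brain peri-infarct against sham, 59 in heart infarct against peri-infarct and 187 in brain infarct against peri-infarct. 34 genes were lower in both organs infarct and 10 in both organs peri-infarct.

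Pericyte-like cells only, with 48 in heart sham, gave these values. 380 genes were lower in heart infarct against sham, 293 in heart peri-infarct against sham and 22 in both organs infarct. Heart infarct against sham had a list median of angiogenic and pericyte-endothelial signalling -0.18. Heart peri-infarct against sham had list medians of matrix proteases and inhibitors 0.67, contractile 0.09 and vasoactive receptors and channels -0.72. Pdgfrb stood at -0.39, Abcc9 at -1.37, Kcnj8 at -1.61 and Ifi27l2a at 2.31 in heart infarct against sham. Nov stood at -0.69, Pdgfrb at -0.29, Mmp2 at 0.85, Abcc9 at -0.98, Kcnj8 at -1.06 and Ifi27l2a at 1.79 in heart peri-infarct against sham.

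Summing pericyte-like and smooth-muscle-like cells together everywhere gave these values. 75 genes were lower in brain infarct against peri-infarct, 23 in both organs infarct and 2 in both organs peri-infarct. Heart infarct against peri-infarct had a list median of dissociation stress -0.28. Acta2 stood at -3.55, Cyr61 at -0.07, Tagln at -4.61, Tpm2 at -1.58, Ndufa4 at -0.68, Klf2 at -0.36 and Atf3 at -0.59 in brain infarct against sham. Acta2 stood at -3.67, Adamts1 at -0.02, Tagln at -4.72, Atf3 at -1.21 and Klf2 at -0.69 in brain infarct against peri-infarct.

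Clustering without the response genes gave these. 15 genes were higher in heart infarct against peri-infarct. 5 genes were lower in heart infarct against peri-infarct. Acta2 stood at -0.20, Tagln at -1.46 and Ndufa4 at -0.12 in brain infarct against sham. Ptgds stood at 0.11 in brain peri-infarct against sham. Fbln1 stood at 0.70, Wisp2 at 2.22, Eln at 1.32 and Cnn1 at 0.24 in heart infarct against peri-infarct. Acta2 stood at -0.76 and Tagln at -2.07 in brain infarct against peri-infarct. In heart sham 0.285% of cells were pericyte-like, 23.3% smooth-muscle-like, 49.96% fibroblast-like and 0.527% unnamed. In heart infarct 9.99% of cells were pericyte-like, 10.9% smooth-muscle-like, 55.4% fibroblast-like and 12.6% unnamed. In heart peri-infarct 5.95% of cells were pericyte-like, 8.05% smooth-muscle-like, 57.3% fibroblast-like and 4.53% unnamed. In brain sham 55.6% of cells were pericyte-like, 6.81% smooth-muscle-like, 13.8% fibroblast-like and 5.76% unnamed. In brain infarct 0.0492% of cells were smooth-muscle-like, 21.6% fibroblast-like and 45.7% unnamed. In brain peri-infarct 46.2% of cells were pericyte-like, 4.58% smooth-muscle-like, 18.6% fibroblast-like and 9.04% unnamed.

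Each library clustered on its own gave these. 40 genes were higher in heart infarct against peri-infarct. 5 genes were lower in heart infarct against peri-infarct. Heart infarct against peri-infarct had list medians of collagen processing -0.16, contractile 0.41 and vasoactive receptors and channels 0.03. Tagln stood at -0.84 and Ndufa4 at -1.19 in brain infarct against sham. Fbln1 stood at 0.36, Wisp2 at 2.34, Eln at 1.37 and Cnn1 at 1.91 in heart infarct against peri-infarct. In heart sham 0.259% of cells were pericyte-like, 23.9% smooth-muscle-like, 27.1% fibroblast-like, 16.3% endothelial-like, 0.251% Schwann-like and 21.8% unnamed. In heart infarct 12.4% of cells were pericyte-like, 5.20% smooth-muscle-like, 11.3% mesothelial-like, 0% cardiomyocyte-like and 3.59% unnamed. In heart peri-infarct 6.31% of cells were pericyte-like, 7.49% smooth-muscle-like, 61.6% fibroblast-like, 0% Schwann-like and 0.836% unnamed. In brain sham 56.5% of cells were pericyte-like, 6.88% smooth-muscle-like, 12.2% fibroblast-like and 7.23% unnamed. In brain infarct 31% of cells were smooth-muscle-like, 28.9% fibroblast-like and 8.71% unnamed.

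A minimum of 1000 genes per cell had these effects. 27 genes were higher in heart infarct against peri-infarct. 7 genes were lower in heart infarct against peri-infarct. 21 matrix genes were higher in heart peri-infarct against sham. Heart infarct against peri-infarct had a list median of contractile 0.33. Tagln stood at -0.76 in brain infarct against sham. Fbln1 stood at 0.46, Wisp2 at 2.44, Eln at 1.36 and Cnn1 at 3.97 in heart infarct against peri-infarct. Acta2 stood at -0.36 and Tagln at -1.17 in brain infarct against peri-infarct. In heart sham 0.872% of cells were pericyte-like, 21.9% smooth-muscle-like, 52.3% fibroblast-like, 17.7% endothelial-like, 0.0312% macrophage-like, 7.20% mesothelial-like, 0% cardiomyocyte-like, 0% Schwann-like and 0% unnamed. In heart infarct 10.4% of cells were pericyte-like, 10.5% smooth-muscle-like, 68.1% fibroblast-like and 0% unnamed. In heart peri-infarct 6.18% of cells were pericyte-like, 7.93% smooth-muscle-like, 62.4% fibroblast-like, 0.561% cardiomyocyte-like, 0% Schwann-like and 0% unnamed. In brain sham 54.8% of cells were pericyte-like and 7.31% smooth-muscle-like. In brain infarct 18.6% of cells were pericyte-like, 0.0520% smooth-muscle-like, 21.3% fibroblast-like and 48.3% unnamed. In brain peri-infarct 5.66% of cells were smooth-muscle-like, 17.7% fibroblast-like and 12.7% unnamed.

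Allowing 20% mitochondrial UMIs had these effects. 73 genes were higher in heart peri-infarct against sham and 10 in brain peri-infarct against sham. 7 genes were lower in both organs infarct and 1 in both organs peri-infarct. Heart peri-infarct against sham had a list median of contractile 0.20. Brain infarct against peri-infarct had a list median of cytokines and inflammation -0.08. Ndufa4 stood at -0.05 in brain infarct against sham. Ptgds stood at 2.05 in brain peri-infarct against sham. Cxcl10 stood at -0.22 and Ccl2 at -1.19 in brain infarct against peri-infarct. In heart sham 32.1% of cells were smooth-muscle-like, 42.5% fibroblast-like, 13.9% endothelial-like, 10.1% mesothelial-like and 0.0555% unnamed. In heart infarct 8.25% of cells were smooth-muscle-like, 65.6% fibroblast-like and 0.551% unnamed. In heart peri-infarct 13% of cells were smooth-muscle-like, 54.6% fibroblast-like, 0.0120% Schwann-like and 0.505% unnamed.

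Male cells only, possible in brain, gave these. 14 genes were higher in brain peri-infarct against sham and 3 in both organs peri-infarct. 188 genes were lower in brain infarct against sham, 52 in brain peri-infarct against sham, 89 in brain infarct against peri-infarct and 9 in both organs peri-infarct. 1 matrix genes were higher in brain peri-infarct against sham. Acta2 stood at -0.66 in brain infarct against sham. Ddx3y stood at 0.05 in brain peri-infarct against sham. Acta2 stood at -1.02 in brain infarct against peri-infarct.

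Free RNA subtracted changed these. 387 genes were higher in heart infarct against sham, 289 in heart peri-infarct against sham and 64 in both organs infarct. 19 matrix genes were higher in heart peri-infarct against sham. Heart peri-infarct against sham had a list median of matrix proteases and inhibitors 0.33. Ifi27l2a stood at 0.39 in heart infarct against sham. Pcolce2 stood at 1.38 and C3 at 1.54 in heart peri-infarct against sham.

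Keeping doublets changed these. 9 genes were lower in heart infarct against peri-infarct and 2 in both organs peri-infarct. Heart peri-infarct against sham had list medians of matrix proteases and inhibitors 0.15, contractile 0.10 and TGF-beta signalling 0.04. Hmgb2 stood at -0.38 in heart infarct against sham. In heart sham 0.249% of cells were pericyte-like, 44.4% smooth-muscle-like, 29.6% fibroblast-like, 14% endothelial-like, 10.6% mesothelial-like and 0.396% unnamed. In heart infarct 12.2% of cells were pericyte-like, 7.76% smooth-muscle-like, 14.5% fibroblast-like and 54.1% unnamed. In heart peri-infarct 6.91% of cells were pericyte-like, 7.19% smooth-muscle-like, 47.6% fibroblast-like, 19.1% endothelial-like and 12.6% unnamed. In brain sham 8.54% of cells were fibroblast-like and 11.2% unnamed. In brain peri-infarct 8.12% of cells were fibroblast-like and 19.6% unnamed.

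The mean of each cell's own CPM changed these. 103 genes were higher in brain infarct against sham. 70 genes were lower in brain infarct against sham and 7 in both organs infarct. Tagln stood at -0.41 in brain infarct against sham. Tagln stood at -0.32 in brain infarct against peri-infarct.

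Thinning each cell to 1000 UMIs changed these. 11 genes were higher in brain peri-infarct against sham and 16 in heart infarct against peri-infarct. Tagln stood at -0.87 in brain infarct against sham. Tagln stood at -0.82 in brain infarct against peri-infarct. In heart sham 30.1% of cells were smooth-muscle-like and 8.29% mesothelial-like. In heart peri-infarct 1.13% of cells were unnamed.

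A minimum of 200 genes changed these. 21 matrix genes were higher in heart peri-infarct against sham. Ndufa4 stood at -0.26 in brain infarct against sham. Ptgds stood at 0.35 in brain peri-infarct against sham. In heart sham 19.1% of cells were smooth-muscle-like, 29.9% fibroblast-like, 13.6% endothelial-like and 26.6% unnamed. In heart infarct 6.44% of cells were smooth-muscle-like, 66.5% fibroblast-like and 1.59% unnamed. In heart peri-infarct 3.00% of cells were unnamed. In brain peri-infarct 19.4% of cells were unnamed.

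TMM factors moved 94 named genes, 6 fibroblast-like counts and 1 other count. 107 genes were higher in heart peri-infarct against sham.

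At Leiden resolution 0.5, 2 named genes, 2 fibroblast-like counts and 8 shares of cells moved. In heart sham 45.2% of cells were fibroblast-like, 0% Schwann-like and 0.0777% unnamed. In heart peri-infarct 0% of cells were Schwann-like. In brain sham 8.78% of cells were fibroblast-like and 10.8% unnamed. In brain peri-infarct 8.34% of cells were fibroblast-like and 19.3% unnamed.

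A pseudocount of 10 CPM moved 1 fibroblast-like count and 1 other count. 4 genes were higher in heart infarct against peri-infarct.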

Other observations

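The genes and comparisons described in this part were chosen after the results were seen, and no explanation of them was tested. Fibroblast-like cells, the largest class sorted from heart, had larger ratios of Col1a1, Postn and Fn1 to sham than the mural cells, in values that have no replicate check, while fewer genes passed 2-fold. The cells compared hardly share clusters: a cluster with 90.6% of the heart sham fibroblast-like cells held 0.686% of those of infarct and 1.27% of those of peri-infarct. In heart, Col1a1 stood at 1147 CPM in sham, 6492 in infarct and 3001 in peri-infarct, and Postn at 270.2, 3572 and 2170.0. Cthrc1 stood at 5.17, 1230.0 and 347 CPM, Lox at 17.7, 866 and 244, Fn1 at 114, 2226 and 596, Timp1 at 94.6, 844 and 440, Cilp at 47.3, 385 and 253 and Comp at 132, 410 and 213. In fibroblast-like cells 213 genes were at least 2-fold higher and 173 lower in heart infarct than in sham, and 88 and 86 in heart peri-infarct.

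In brain, fibroblast-like cells of the infarct carried Spp1 at 19080.0 CPM against 47.2 in sham and 340.4 in peri-infarct, and Col1a1 at 6613 against 1024 and 996. Col3a1 stood at 5306 against 363 and 274 CPM, Timp1 at 1680.0 against 57.0 and 78.2 and Mmp3 at 648 against 0 in both other libraries, while Postn was even at 141 against 139. Most of these infarct cells, 258 of 309, sat in a cluster with 0 cells of the other libraries. The unnamed collagen-rich clusters of brain infarct carried Col1a1 at 7614 CPM, Spp1 at 7326, S100a6 at 3934, Timp1 at 2125, Cthrc1 at 1471 and Acta2 at 1263. In brain, 436 genes were higher and 710 lower in fibroblast-like cells of infarct, and 25 and 82 in peri-infarct. This balance depends on the scaling, since with TMM factors 1064 genes were higher and 327 lower in brain infarct against sham, and 39 and 36 in brain peri-infarct against sham. With at least 1000 genes per cell the peri-infarct counts were 97 and 271.

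Some barcodes occurred in more than 1 library, 204 of them in both heart and brain peri-infarct and 133 in both brain injury libraries. A heart cluster of 59 cells led by Ptgds had a median of 789 UMIs, and 96.6% of its barcodes also occurred in a brain library. This cluster was unnamed and in no comparison. Heart cells carried Xist, with 1, 2 and 0 cells holding Y-linked UMIs alone in infarct, peri-infarct and sham. Brain peri-infarct held 485 cells with Y-linked and 1082 with Xist UMIs alone, and 43 with both. Between female and male pericyte-like cells of the same library, 33 genes were at least 2-fold higher and 28 lower in brain infarct, and 16 and 15 in brain peri-infarct.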
